A study of Drosophila melanogaster with 3 samples.

How the data were processed

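RNA from Drosophila melanogaster larvae, wandering and pooled according to the labels' protocols, was measured by sequencing in 3 libraries. The control library has the Actin5C-Gal4 driver and no RNAi in its label (Act>control), the RNAi library adds a UAS hairpin against Aac11 (Act>Aac11-RNAi), and a further library is labelled enGFP+Yki+Aac11-IR (called here the Yki library). Per the labels' protocols, animals were raised at 25 degrees Celsius with 12 hours of light, were sorted by GFP fluorescence and ground whole in Trizol, and 10 to 20 larvae were collected for each of the Act genotypes. The number of animals in the Yki library is not given in the sources used here. From 4 µg of total RNA, depleted of ribosomal RNA, a TruSeq RNA v2 library was made. The source label of every sample reads wing disc cells, whereas the extraction protocol describes whole larvae. No label resolves this, so both descriptions are stated.

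The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the size of the library) for 13990 genes in 2 tables, 1 with both Act libraries and 1 with the Yki library. The submitters' processing notes name CASAVA 1.4, TopHat2 2.0.12, Cuffdiff 2.2.1 and the genome build dm6, without saying which step each did. Near-identical copies, as among cecropin, cuticle protein, histone and snoRNA genes, can share reads, so single values there are uncertain, and overlapping or antisense genes cannot be told apart. The annotation, the strand setting and the scaling between libraries are not given in the sources used here. All deposited per-sample columns were used. Because the tables were normalized separately, no ratio was formed between them, and levels in the Yki library are given as FPKM or as ranks within that library.

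Every group has 1 library, so there are no replicates, and no p-value, standard error or standard deviation is given anywhere. The log2 ratio is log2 of (RNAi FPKM + 1) over (control FPKM + 1), which understates changes of genes near 0. Genes were kept when their mean FPKM over the Act libraries was at least 1, and were called higher or lower at 2-fold. A value of 0 in a file without counts can be a failed estimate, so such genes are described as listed at 0 and no fold is formed for them, although their log2 ratio enters counts and medians with the pseudocount.

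The sequencing depth was estimated from the FPKM steps. Among 4251 genes with 1 annotated transcript longer than 1000 nt, low values lay at multiples of a step that scaled with transcript length. In the control, RNAi and Yki libraries 82.4%, 85.1% and 88.9% of low values fell within 0.2 of a whole fragment, where 40% would by chance. Fragments of single-transcript genes longer than 400 nt were read back from this step, and exact binomial 95% intervals of a ratio cover counting error only. Transcript lengths and coordinates came from the Ensembl 115 annotation of the Release 6 genome (BDGP6.54), which shares coordinates with dm6. Symbols were matched to the NCBI RefSeq gene table for the Release 6 assembly, which recognised 13734 of them, 98.2% of the total, and 98.4% of the kept genes had a transcript length.

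The 35 gene lists and all main settings were fixed before the data were examined. A list needed 5 kept members. Its median log2 ratio was placed among medians of 10000 random lists with the same number of genes in each of 20 bins of mean expression, and was called above or below outside the central 95%. These percentiles describe these libraries and do not test the conditions. The list of mitochondrially encoded genes matched 0 genes in the tables. Named genes followed a rule. It took Aac11, the 12 largest rises and 12 largest falls among genes with a mean FPKM of at least 5, and up to 2 members of each list each way. For the Yki library it took Aac11, yki, en, the 10 highest genes and up to 3 highest members of each list. Because small structural RNAs filled all 12 places of the largest rises, the same ranking without them was added after seeing the data, and other genes named outside the rule are said to be so where they appear.

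Alternatives fixed in advance were pseudocounts of 0.1 and 5 FPKM, 3 rescalings (median log2 ratio set to 0 over genes of at least 10 FPKM, sums set to 1000000, and equal upper quartiles), no filter, a filter at 5 FPKM, 10 matching bins and the list mean. Alternatives added after seeing the data matched random lists on transcript length (5 bins of level with 10 of length in each), kept only genes of at least 1 FPKM in the Yki library, left out small structural RNAs, or subtracted the median of each of 10 transcript length bins. On simulated data with known depths of 6, 30 and 18, in units of 1000000 fragments, the depth step returned 5.98, 30.0 and 18.0 from 3245 genes. Of 200 genes simulated at 4-fold among 2475 genes, 100% were recovered. Of random lists drawn from 2275 unchanged simulated genes, 5.5% fell outside the central 95%. The simulation held no transcript length trend, so it checks the calculation and not the calls on the real lists. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.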

Results

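The series asked how loss of Aac11 changes RNA levels in Drosophila larvae. Aac11, the fly ortholog of mammalian API5 (apoptosis inhibitor 5), was targeted by an RNAi hairpin under Actin5C-Gal4, a driver active in most tissues. Expression was given as FPKM for 13990 genes in 1 Act>control library, 1 Act>Aac11-RNAi library and 1 Yki library, whose label names engrailed-GFP, Yorkie and the Aac11 hairpin. There were no replicates, so every difference below lacks a replicate check and describes these libraries. The FPKM steps gave depths of about 5900000 fragments for the control, 31000000 for the RNAi library and 17700000 for the Yki library. At 1 kilobase of transcript, 3 fragments correspond to 0.506 FPKM in the control, 0.0967 in the RNAi library and 0.169 in the Yki library, so low values are least precise in the control.

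Aac11 RNA was lower in the RNAi library. The gene (FBgn0286781, current symbol cass) lies on chromosome 2L from 17474912 to 17477888 on the minus strand of the Release 6 (dm6) genome and has 1 annotated transcript of 2458 nt. It measured 150 FPKM in the control and 78.1 FPKM in the RNAi library, a log2 ratio of -0.93 with the pseudocount. About 2008 and 5470 fragments lay behind these values, and the 95% counting interval of the log2 ratio, without a pseudocount, ran from -1.01 to -0.87. With upper quartiles set equal the log2 ratio was -0.62. In the Yki library, normalized separately, Aac11 measured 117 FPKM.

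Testis RNA was lower in the RNAi library. Of 33 testis genes kept, 31 were at least 2-fold lower in the RNAi library, 0 were higher, and the list median was -1.89, below the central 95% of random lists (-0.22 to 0.10). Mst98Ca, a sperm-tail protein gene, went from 348 to 71.8 FPKM, and Tim17a1, a testis form of a mitochondrial import subunit, from 35.9 to 6.66 FPKM. The smallest differences in the list belonged to mia, at 6.66 and 5.34 FPKM, and aly, a regulator of spermatocyte transcription, at 5.25 and 2.36 FPKM. Among genes chosen after their values were seen, Mst87F went from 1041 to 290 FPKM and betaTub85D, the testis beta-tubulin, from 466 to 123 FPKM.

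The roX RNAs and the kept Y-linked genes were lower along with the testis genes. The noncoding RNAs of the male dosage compensation complex were lower, roX1 (chromosome X, 3857230 to 3862697) at 161 and 37.0 FPKM and roX2 (chromosome X, 11579065 to 11580432) at 104 and 17.2 FPKM. The sex-determination genes Sxl, at 44.0 and 44.3 FPKM, and tra, at 23.4 and 23.4 FPKM, had log2 ratios of 0.01 and 0.00. Chosen after their values were seen, msl-2, a dosage compensation gene, measured 18.2 and 11.4 FPKM, and the yolk protein gene Yp3, counted here as female-limited, was lower at 9.35 and 2.69 FPKM. The list of dosage compensation RNAs and female-limited genes had a median of -1.06 over 6 members, at percentile 1.77. This list pools the roX RNAs, msl-2, Yp3 and the sex-determination genes, so its median gives no direction for the sex mix. The FPKM values are per gene and do not separate transcript forms, so the similar Sxl and tra levels do not measure the female share. Y-linked genes, a list added after the values were seen, had all 5 kept members at least 2-fold lower, among them ARY from 17.1 to 4.54 FPKM and Pp1-Y2 from 11.8 to 2.29 FPKM. Among Y-linked genes under the filter, the dynein genes kl-3, kl-2 and kl-5 had log2 FPKM ratios without a pseudocount of -2.35, -1.24 and -0.49. The counting intervals ran from -1.66 to -0.80 for kl-2 and from -0.95 to 0.00 for kl-5, which measured 0.614 and 0.438 FPKM.

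In all, 419 of 11330 kept genes were at least 2-fold higher and 1921 at least 2-fold lower in the RNAi library. Most of the lower genes measured little in the Yki library. Of the 1921, 87.3% had under 1 FPKM there, compared with 22.2% of the other kept genes. That level did not single out testis genes, since 30 of 33 testis genes, 29 of 35 immune genes and 17 of 23 neuron genes were under it. At least 2-fold lower, however, were 31 of the testis genes, 1 of the immune genes and 0 of the neuron genes. Lower genes with a mean of at least 10 FPKM had a narrow spread, with log2 FPKM ratios of -2.05, -1.92 and -1.75 at their quartiles. The testis list had similar quartiles without a pseudocount, at -2.02, -1.91 and -1.79. Restricted to genes of at least 1 FPKM in the Yki library, a choice made after seeing the data, the counts were 204 higher and 244 lower. With upper quartiles set equal, 819 genes were higher and 1704 lower, so that the higher genes made up 32.5% of the calls against 17.9% as deposited.

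**Figure D1:**
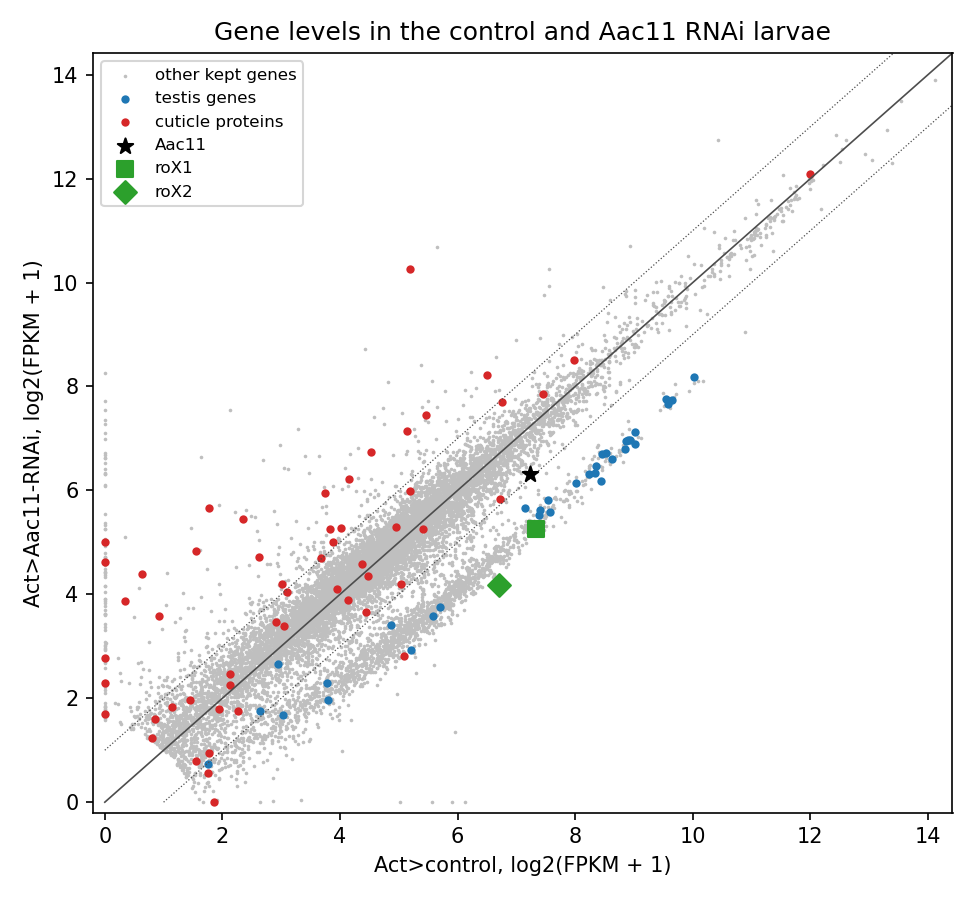
Levels of 11330 kept genes in the control (x axis) and RNAi library (y axis), both as log2(FPKM + 1), with testis genes, cuticle protein genes, Aac11, roX1 and roX2 marked; the solid line is equality and dotted lines mark 2-fold. A separate band of genes lies below the lower dotted line, holds 31 of the 33 testis genes and passes roX1 at 161 and 37.0 FPKM, while cuticle protein genes scatter upwards.

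The largest rises by rule were 12 small structural RNAs, each listed at 0 in the control, led by the 7SK RNA gene snRNA:7SKa (304 FPKM in the RNAi library) and snoRNA:Psi28S-3091a (209 FPKM). Of 100 kept small structural RNAs, 58 were higher and 18 lower by 2-fold, with snoRNA:Psi18S-1347a at 69.1 FPKM in the control and listed at 0 in the RNAi library. The list median of 3.40 depended on the pseudocount, at 6.59 with 0.1 FPKM and 1.64 with 5 FPKM. Leaving out all small RNAs recognised by list or name, 59 of them higher, with 56 listed at 0 in the control, and 18 lower, gave 360 higher and 1903 lower genes. Ranked without them, a choice made after seeing the data, the rises were led by CG11413, from 3.35 to 186 FPKM, the cuticle protein gene Cpr100A (chromosome 3R, 30867521 to 30869184), from 35.4 to 1224 FPKM, and CG12998, from 49.2 to 1654 FPKM. Others were CG34454 (2.10 to 98.4 FPKM), CG13722 (20.6 to 422 FPKM) and CG13618 (5.47 to 94.5 FPKM). Cpr65Ec and Edg84A were listed at 0 in the control and measured 31.4 and 23.8 FPKM in the RNAi library. The falls were led by CG42852, at 31.4 FPKM and then listed at 0, and CG15892, from 61.0 to 1.55 FPKM. They also held CG3397 (47.3 to 5.21 FPKM), RpS28-like (38.2 to 4.61 FPKM), roX2 and the proteasome paralog Prosbeta4R2 (37.8 to 5.96 FPKM).

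Among the 34 gene lists, that of cuticle proteins held the most protein-coding genes on the higher side. Of 54 kept members of the larval and pupal cuticle list, 24 were at least 2-fold higher and 3 lower, and the median of 0.77 lay above random lists (-0.20 to 0.14). Besides Cpr100A, Edg78E went from 12.4 to 60.4 FPKM and Lcp4 from 4.12 to 42.6 FPKM, both chosen after their values were seen. The opposite direction was seen for Twdlalpha, from 32.9 to 6.07 FPKM, and for Lcp65Aa, at 2.62 FPKM and then listed at 0. Testis and roX RNA were lower in the same library.

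Immune genes were higher in the RNAi library for 13 of 35 kept members, and 1 was lower, with a list median of 0.49. The Bomanin gene IM3 went from 3.64 to 46.7 FPKM, and IM1 was listed at 0 and then measured 11.1 FPKM. Cecropin genes, named after their values were seen, included CecC, from 73.7 to 310 FPKM. The exception was dro5, a drosomycin-like gene, from 474 to 161 FPKM. These genes measured little in the Yki library, where CecC was at 0.326 FPKM.

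Ecdysone response genes had 4 of 33 kept members at least 2-fold higher, 0 lower and a median of 0.46. The larval-to-pupal transition factor br went from 6.64 to 23.4 FPKM and Eig71Ek from 8.0 to 32.8 FPKM, while ImpE2 measured 2629 and 1558 FPKM. Ecdysone synthesis genes, among them the hydroxylase gene phm at 15.9 and 28.1 FPKM, had a median of 0.39 and 0 members past 2-fold. Most replication genes had small positive log2 ratios. Of 36 kept E2F1 target and DNA replication genes, 32 were positive, 4 were negative and the median was 0.44. RnrL, a ribonucleotide reductase subunit gene, was the 1 member past 2-fold, at 16.5 and 34.7 FPKM, and Sld5 measured 14.2 and 10.5 FPKM. Mitosis genes had a median of 0.09, inside the random range.

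Genes of the Hippo pathway, which restrains the transcriptional coactivator Yorkie, had a median of 0.34 over 32 members and 0 members past 2-fold. All 19 kept Yorkie targets had positive log2 ratios, with a median of 0.35. Of these, dm, which encodes Myc, went from 2.51 to 11.8 FPKM, and th, which encodes the caspase inhibitor DIAP1, measured 280 and 296 FPKM. Both lists came inside the random range when random lists were matched on transcript length, at percentiles 80.8 for the targets and 93.1 for the pathway. Wing disc patterning genes (median 0.30) and fat body genes (median 0.18) also came inside, at percentiles 94.0 and 78.8. Within the fat body list, Lsp1alpha, a larval serum protein gene, was lower at 207 and 86.2 FPKM, and Lsp1gamma measured 156 and 308 FPKM.

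Apoptosis regulators, which control the process named in mammalian API5, had a median of 0.20 at percentile 97.8. The caspase gene Damm went from 1.09 to 4.29 FPKM and AIF from 47.3 to 23 FPKM, while dream measured 9.25 and 16.4 FPKM. With upper quartiles set equal the percentile was 97.1, inside the random range. Splicing and mRNA export genes, which include the Acinus gene hkl at 67.8 and 79.0 FPKM, had a median of 0.00 at percentile 65.8 and 0 members past 2-fold.

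Several further lists lay above random lists. JNK and regeneration genes had a median of 0.38, with the matrix metalloprotease gene Mmp1 going from 66.9 to 198 FPKM and chinmo from 6.18 to 2.38 FPKM. In insulin and nutrient signalling (median 0.36), InR went from 2.36 to 6.43 FPKM and Ilp5 from 0.620 to 3.35 FPKM, the latter on 1 control fragment. Neuron genes had positive log2 ratios in all 23 kept members and a median of 0.50, with the tyrosine hydroxylase gene ple going from 1.05 to 12.8 FPKM and Vmat from 2.83 to 10.2 FPKM. Heat shock and chaperone genes had a median of 0.21 with 0 members past 2-fold, and Hsp68 measured 59.8 and 97.3 FPKM. The salivary gland and midgut lists rested on 6 kept members each, with medians of 0.68 and 0.52. With genes under 1 FPKM in the Yki library left out and length matched, the neuron and salivary gland lists came inside the random range, at percentiles 94.2 and 90.5. In the midgut list, the lysozyme gene LysD went from 28.9 to 102 FPKM.

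Besides the testis and dosage compensation lists, respiratory chain, mitochondrial ribosome, proteasome and germline lists lay below random lists. Oxidative phosphorylation genes had 85 of 87 members with negative log2 ratios, 20 of them past 2-fold, and a median of -0.49. Of these 20, 18 had under 1 FPKM in the Yki library. The largest falls were of CG30093 (current symbol COX6AL, a cytochrome oxidase subunit-like gene), from 57.8 to 10.6 FPKM, and CG7211 (current symbol ATPsynGL), from 74.1 to 15.4 FPKM. Both were listed at 0 in the Yki library. The 68 members of at least 1 FPKM in the Yki library had a median of -0.41, at percentile 0. Mitochondrial ribosomal protein genes had a median of -0.38 over 72 members and 0 past 2-fold, and came inside the random range with length matching alone, at percentile 51.3, but lay at 0.03 when genes under 1 FPKM in the Yki library were also left out. Proteasome genes had a median of -0.30. With upper quartiles set equal it was 0.02 and still below random lists, at percentile 0.12, and with length matching it came inside, at 3.26. Of their 15 lower members, 14 had under 1 FPKM in the Yki library. Among these were Prosbeta4R2 and Pros28.1B (current symbol Prosalpha4T2, 47.1 to 10.3 FPKM), both listed at 0 there. The 32 proteasome genes of at least 1 FPKM in the Yki library had a median of -0.08, inside the random range at percentile 17.7. Germline and piRNA genes had a median of -0.37 at percentile 1.29, and 4.92 among genes of at least 1 FPKM in the Yki library, with bgcn going from 8.32 to 2.62 FPKM and mael from 14.6 to 6.22 FPKM. Testis and roX RNA were lower in the same library.

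**Figure D2:**
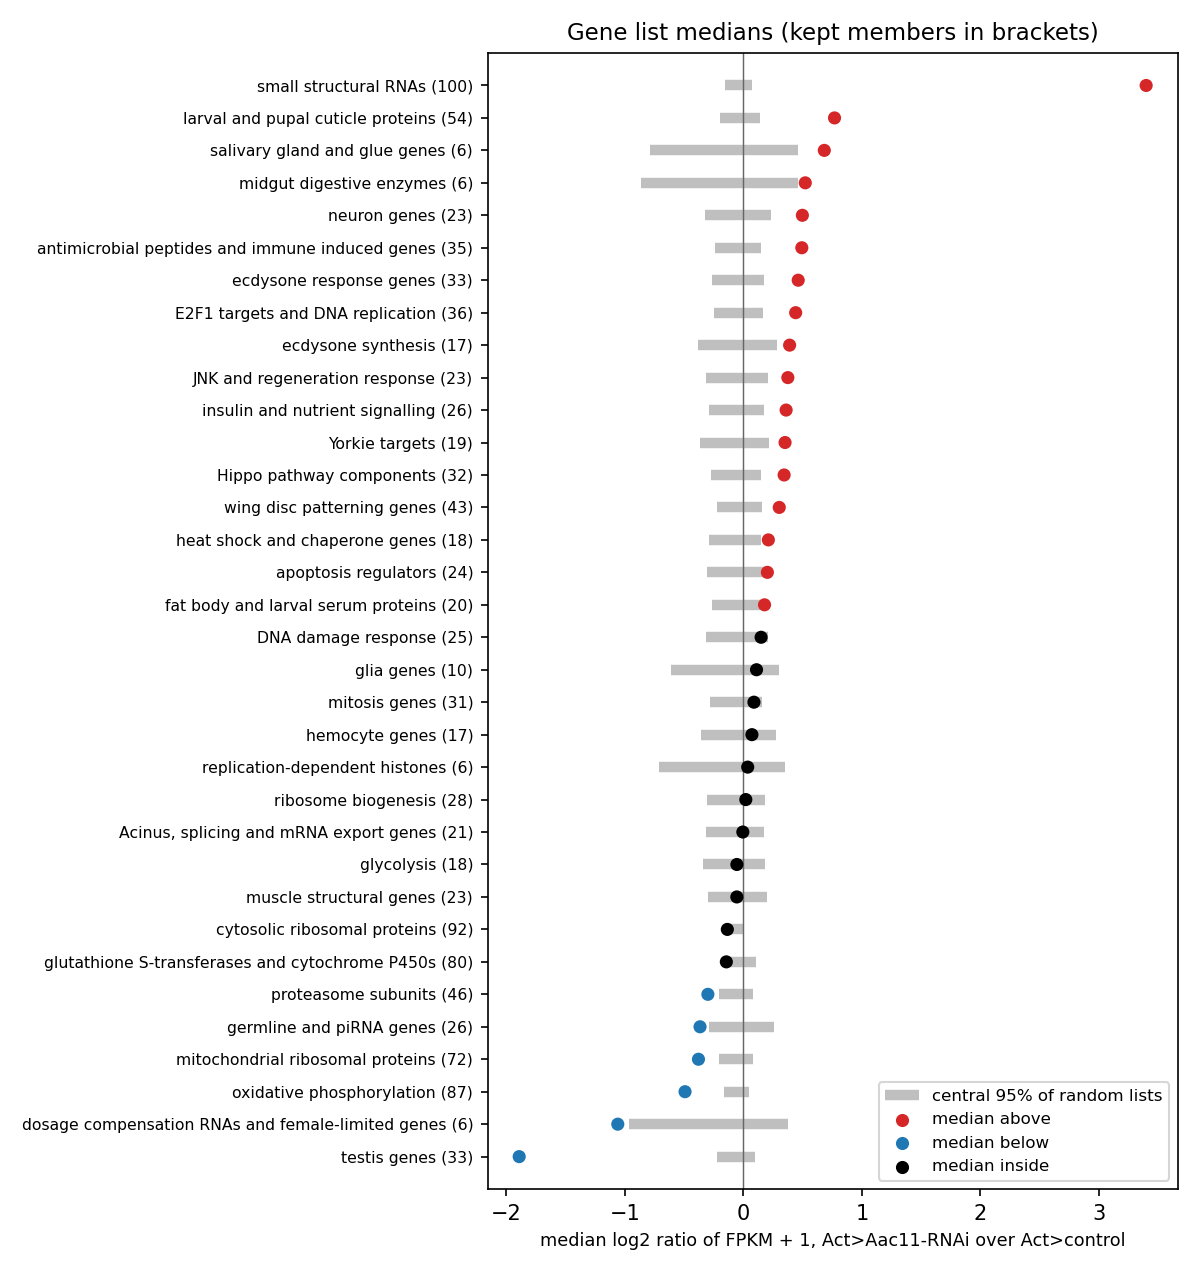
Median log2 ratio of FPKM + 1 (RNAi over control) for each of 34 gene lists, with grey bars for the central 95% of 10000 random lists matched on mean expression. Of these lists, 17 lie above the bar, 6 below and 11 inside, from -1.89 for testis genes to 3.40 for small structural RNAs, a value set by the pseudocount of 1 FPKM.

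The other lists lay inside the random range. Their medians were -0.14 for cytosolic ribosomal proteins and for glutathione S-transferases and cytochrome P450s, -0.06 for muscle, -0.05 for glycolysis, 0.02 for ribosome biogenesis, 0.04 for histones, 0.07 for hemocytes, 0.11 for glia and 0.15 for DNA damage response. Cytosolic ribosomal proteins moved outside under some settings, below with upper quartiles set equal (percentile 1.99) or with genes under 1 FPKM in the Yki library left out (0.35), and above with length matching (97.52). Glutathione S-transferases and cytochrome P450s lay below with no filter (1.53) or with that restriction (0.59), and hemocyte genes lay below with the restriction and length matching together (1.73). The negative medians among these lists turned positive with upper quartiles set equal, a scaling that moved the median of all kept genes by 0.29 and the random ranges with it, so these signs describe the scaling and not the lists. Members past 2-fold in these lists included Mlc1, a muscle myosin light chain gene, from 114 to 42.3 FPKM, Cyp12a4 from 14.7 to 2.0 FPKM and the lactate dehydrogenase gene ImpL3 from 11.1 to 41.2 FPKM.

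Log2 ratios rose with transcript length across genes. Among kept genes of at least 1 FPKM in the Yki library, the median was -0.21 in the decile with the shortest transcripts and 0.43 in the decile with the longest. Spearman's rho across these 7433 genes was 0.449, and genes are not independent replicates. Neuron, Hippo and Yorkie target genes have long transcripts, with list medians of 6920, 4573 and 4792 nt, and cytosolic and mitochondrial ribosomal protein genes have short ones, at 858 and 778 nt.

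**Figure D3:**
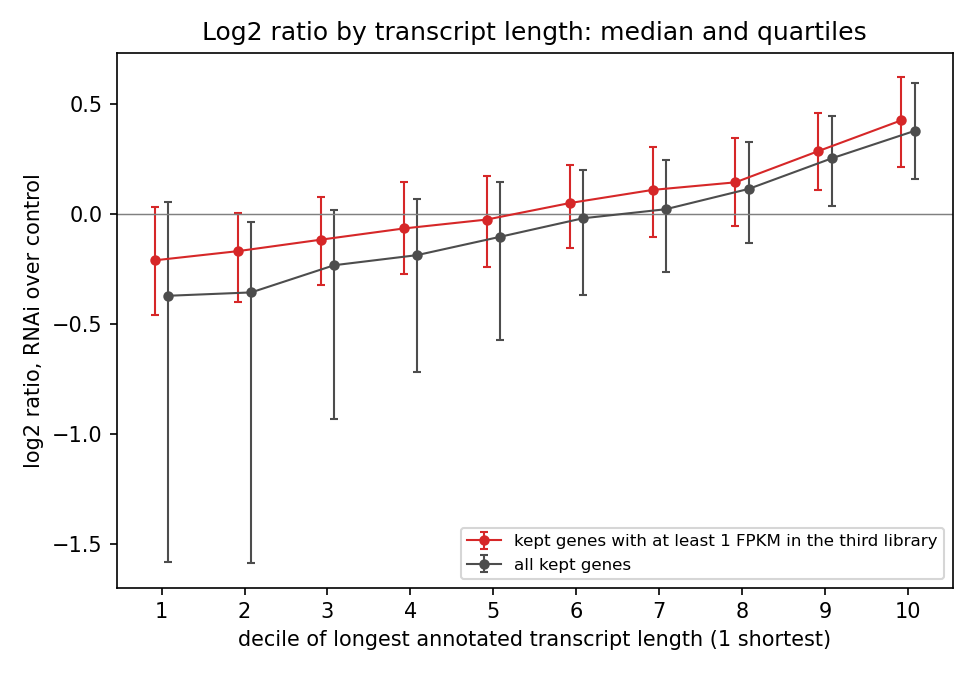
Log2 ratio (RNAi over control) by decile of the longest annotated transcript, as medians with quartiles, for all kept genes and for kept genes of at least 1 FPKM in the Yki library. Medians of the latter run from -0.21 in the shortest decile to 0.43 in the longest.

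The Yki library was described on its own, since no library with the same driver and without the hairpin was analysed here. Its yki level was 4153 FPKM, beside 64.3 FPKM in the control and 59.7 FPKM in the RNAi library of the separately normalized table, and en, the gene of the posterior compartment, measured 30.8 FPKM. The highest genes were translational, with RpL41 at 31036 FPKM, RpL39 at 16209 FPKM and the elongation factor gene Ef1alpha48D at 7979 FPKM. The labels name wing disc cells but describe whole larvae, and do not settle whether all 3 libraries came from the same tissue. The testis list median was 299 FPKM in the control and 0.102 FPKM in the Yki library, and the fat body list median 184 and 3.58 FPKM. Male RNA was present in both, with roX1 at 161 and 179 FPKM. Although the tables were normalized separately, these levels argue against an equal tissue content. A rank difference from the control is thus not one of genotype alone. Proliferation genes ranked high within this library. The median rank was percentile 81.5 for E2F1 targets and replication, compared with 42.7 in the control, and 89.4 for mitosis genes, compared with 58.5, with dUTPase at 544 FPKM and polo at 246 FPKM. Yorkie targets ranked at percentile 84.9, with ex at 228 FPKM and dally at 131 FPKM, and wing disc patterning genes ranked at 75.4, with fng at 138 FPKM. Ribosome biogenesis genes ranked at 89.7, with Nop60B at 339 FPKM. More genes were listed at 0 in the Yki library, 3460 compared with 1571 in the control, which raises the ranks of genes above 0. Germline genes ranked at 48.7 compared with 28.9 in the control, although their median FPKM was 2.53 and 3.66 in these separately normalized tables.

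Testis, fat body, muscle, glia and immune genes ranked lower in the Yki library than in the control, and the same limit on tissue content applies. Testis genes had a median rank of percentile 32.7, compared with 97.1 in the control, and 3 of 33 reached 1 FPKM. Fat body genes ranked at 50 compared with 95, muscle genes at 42.7 compared with 66.2, glia genes at 45.6 compared with 62.2, and immune genes at 12.4, the rank of genes listed at 0, compared with 50.3. Neuron and hemocyte genes had similar median ranks in both, at 30.7 and 43.5 compared with 32.4 and 39.7, but fewer reached 1 FPKM in these separately normalized tables. That level was reached by 6 of 25 neuron genes compared with 21 in the control, and by 9 of 20 hemocyte genes compared with 18. Salivary gland and midgut genes had a median of 0 FPKM in the control, where 4 of 18 and 6 of 46 reached 1 FPKM, so their ranks were not compared. Among the fat body and muscle genes, Lsd-2 measured 301 FPKM and Tm1 491 FPKM. The male dosage compensation RNA roX1 measured 179 FPKM and roX2 114 FPKM. These ranks were taken within each library.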

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

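The settings that matched transcript length, required 1 FPKM in the Yki library, left out small RNAs or subtracted length medians were chosen after seeing the data. With length medians subtracted the Aac11 log2 ratio was -0.98. It was also negative under all 5 alternatives fixed in advance and run on it. Under 2 of these it moved beyond its counting interval, to -0.80 with sums set to 1000000 and -0.62 with equal upper quartiles. Those scalings moved the median of all kept genes by 0.13 and 0.29. The number of genes at least 2-fold higher, 419 as deposited, was 245 with a pseudocount of 5 FPKM and 819 with equal upper quartiles. Restricting to genes of at least 1 FPKM in the Yki library gave 204 higher and 244 lower genes, by construction fewer. Of 34 gene lists, 17 lay above random lists, and 10 did with that restriction and length matching together; all 10 were among the 17. With a pseudocount of 5 FPKM the apoptosis, germline, midgut and dosage compensation lists came inside, with no filter the germline, midgut, dosage compensation and small RNA lists, and with a filter at 5 FPKM the germline list, while the salivary gland and midgut lists had too few members there. With the list mean the apoptosis, germline, fat body, heat shock and mitochondrial ribosome lists came inside, and with equal upper quartiles the apoptosis list. Calls were also gained. Cytosolic ribosomal proteins went below with equal upper quartiles and with genes under 1 FPKM in the Yki library left out, and above with length matching. Glutathione S-transferases and cytochrome P450s went below with no filter and with that restriction, and hemocyte genes with the restriction and length matching together. The median-set and sum scalings, the pseudocount of 0.1 FPKM and the 10 matching bins changed the call of 0 lists. No named gene changed the sign of a 2-fold call. With the pseudocount of 5 FPKM, 13 of 166 named genes no longer reached 2-fold, and with equal upper quartiles 6 no longer did and 20 newly did. The causes of the shifts with scaling were not tested. The midgut and testis lists kept under 5 members at 1 FPKM in the Yki library and gave no value there. The control library, at about 5900000 fragments, limits the precision of low genes.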

Other observations

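The tests on testis, roX and transcript length were chosen after their result was seen. Those on cuticle stage and fragment number were chosen before their own result was seen, but after the higher cuticle RNA had been found in these data.

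Some genes for chitin and cuticle assembly outside the fixed lists were also higher in the RNAi library. Of 30 kept members with a transcript length on a list of tanning, chitin and apical matrix genes, 9 were at least 2-fold higher and 0 lower. Gasp, a chitin-binding protein gene of the tracheal matrix, went from 32.4 to 179 FPKM, the chitin deacetylase gene serp from 8.51 to 41.3 FPKM, and the chitinase gene Cht7 from 12.0 to 50.1 FPKM. The chitin synthase gene kkv went from 62.2 to 131 FPKM, whereas Cht5 measured 1925 and 1389 FPKM. Several tanning and pigment genes on the list differed little, with log2 ratios of -0.17 for Pu, 0.08 for e, 0.06 for t and 0.00 for yellow-d, whereas yellow-h was at 1.58 and CG42345, the laccase gene stw, at 1.03. The apical matrix genes mey and tyn were at -0.65 and -0.21. The tyrosine hydroxylase gene ple, counted above with the neuron genes, was not on this list and went from 1.05 to 12.8 FPKM.

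Lower testis, roX and Y-linked RNA in the RNAi library may reflect a smaller share of male RNA in the pool of larvae. The mean log2 FPKM ratio of roX1 and roX2, which are made in male body cells, was -2.36, beside a testis list median of -1.91 without a pseudocount. The Y-linked gene kl-5 was at -0.49 (interval -0.95 to 0.00), which a smaller male share alone leaves unexplained. With the pseudocount kl-5 was at -0.17, and at -0.59 with the median of its transcript length bin subtracted. The yolk protein gene Yp3 was also lower, but these data do not show whether it was female-limited in these larvae. Less testis tissue with an unchanged share of males would leave the roX RNAs in place, but the smaller of their falls was -2.12, with a counting interval from -2.19 to -2.05. The difference between the testis list median and the 2.5th percentile of random lists matched on transcript length was -1.61, which argues against the length trend as the whole cause. An effect of Aac11 on male larvae, such as fewer surviving males, and an accident of which larvae were pooled both stay open, because the sex of the larvae is not given in the labels. Whether a smaller male share also underlies the other lower genes was not tested.

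Of the 17 list medians above random lists, 4 could come from the transcript length trend (ended calls), since matching on length raised the random range around the Yorkie target, Hippo, fat body and wing disc medians. In the other 13 (remaining calls) the median stayed above, and 10 stayed above when genes under 1 FPKM in the Yki library were also left out. Apart from the small structural RNAs, length is not the whole cause in the lists that stayed above under both settings. The neuron and salivary gland lists came inside with the restriction, and the midgut list gave no value, so length stays open for these. The small structural RNAs had a median length of 141 nt, while the shortest decile of all kept genes ran from 113 to 724 nt. Matching was therefore too coarse for them, and a part played by length stays open there. Whether the trend itself came from RNA quality, library preparation or the larvae was not tested. Apart from the cuticle list, no biological explanation was tested for these lists.

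Higher cuticle RNA may reflect a later stage of cuticle formation in the RNAi pool. The separate tanning, chitin and apical matrix list lay at percentile 99.6 among length-matched random lists, although several of its tanning and pigment genes differed little and its 9 members past 2-fold were mostly chitin genes. The same matching placed 14 of 34 gene lists above random lists, so a place above was common and does little to single out stage. The length trend is not the whole cause, since the cuticle median stayed 1.04 above that of matched random lists, which was -0.27. The size of this gap depends on the genes drawn, which include the many lower genes with short transcripts. Among genes of at least 1 FPKM in the Yki library, the cuticle median was 0.52 over 21 members, beside -0.15 for length-matched random lists. Low fragment numbers in the control are not the whole cause either. Over all 40 kept single-transcript cuticle genes, 23 counting intervals lay above equal levels, 5 below and 12 included them. Of the 17 such genes at least 2-fold higher, picked by the same ratio, 17 had an interval that excluded equal levels. Whether stage differed through Aac11 or through the timing of collection stays open, with 1 pool per genotype.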
